A study of Homo sapiens with 3 samples.

How the data were processed

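Total RNA from MIA PaCa-2 cells, grown as a monolayer to 100% confluency or as spheroids for 6 or 13 days in RPMI medium with 10% fetal bovine serum, was extracted with TRIZOL, treated with DNase, amplified and labelled with Cy3, per the labels' protocols. Each of the 3 samples was hybridised to 1 array of a whole human genome design, and all 3 arrays lay on 1 slide and were read in 1 scan, so slide and scan do not separate the groups. The labels give no replicates and no culture day for the monolayer.

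The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 11.5.1.1 (protocol GE1_1105_Oct12), per the file headers. The processed signal is background-subtracted and was not scaled between arrays. The deposited table of the whole series holds an intensity per probe as well. Its values equalled the mean of the processed spot signals within a relative tolerance of 0.0001 for 33962, 33966 and 33959 probes (monolayer, day 6 and day 13), so its scale is linear and it is neither centred nor a ratio. Its medians were 130, 73.3 and 73.3 units, and it was used as an alternative.

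Each array held 43118 non-control spots for 34127 probes. From these files the log2 processed signal was computed, spots with a non-uniformity or population outlier flag were dropped (237, 177 and 166 spots), and spots of a probe were averaged. The 75th percentile over the averaged values of the non-control probes of each array was then subtracted. Of the probes, 25767 had their accession matched to 1 gene symbol through a RefSeq gene table and 8360 to none. This gave 19736 genes. The table and the array grid use different genome assemblies, so no coordinates are given. Probes left out because all their spots on an array were outliers numbered 6. For the 4994 genes with more than 1 probe, the probe with the highest mean over the arrays was used. A gene was measured in a comparison when at least 50% of its probe's spots were well above background on at least 1 of the 2 arrays. A side not well above background was set to the higher of its own value and the lowest value well above background on that array, and the difference is then a bound, written as at least N-fold. Where such a bound fell under 1 it was set to 0 difference. Among genes with several measured probes the SD between probes had a median of 0.30, 0.37 and 0.18 log2 units in the 3 comparisons, and 129 of 1046, 154 of 1297 and 40 of 344 genes past 2-fold had probes of opposite sign.

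With 1 array per group, differences are described by size: at least 2-fold higher or lower. The comparisons (day 6 and day 13 against monolayer, day 13 against day 6), the 34 gene lists, the rule for named genes and all alternatives except those listed as later below were fixed before the data were examined. The rule names, per comparison, the 12 highest and 12 lowest differences measured on both arrays, the 3 largest bounds in each direction, and up to 4 members of each list by size, of which the text may give a part. Some genes that the rule names are not reported here. A list's median was ranked among 10000 random lists of the same size drawn from 20 bins of mean log2 value. This rank describes these arrays and is not a test over samples.

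The alternatives were each array's median, quantile normalization or cyclic loess as the scaling, normexp background correction (offset 50) with the 75th percentile or with quantile normalization, the series table's values, well above background on both arrays, no filter and no floor, the mean over all probes of a gene, outlier spots kept, and for list ranks 10 bins or no matching. Normexp was run on the median spot and local background signals, since the files used here hold no mean signal. A block for slide or scan was planned and not run. After seeing the data, 2 alternatives were added: the upper 50% of genes by mean signal, and 30 units subtracted from every probe with values below 10 set to 10. Gene families named in the closing section were also chosen after seeing the data, and so was the split by monolayer signal of a list of leukocyte genes used there.

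The steps were tested on simulated arrays with genes changed by known folds. With equal brightness, 98% of genes made 3-fold higher and 98% made 3-fold lower were called for day 6 against monolayer (50 genes each), and with spheroid arrays made 3-fold dimmer, 100% and 78%. For day 13 against monolayer the shares were 100% and 94%, then 100% and 80%. In these simulations dim arrays thus lost some lower calls. On the dimmer arrays, 34 of 15250 unchanged genes on day 6 and 40 of 15217 on day 13 were called higher, and 0 lower. Few simulated genes thus behaved like the dim genes of the measured arrays, whose difference from monolayer before scaling was near 0. The simulated shares therefore give no error rate for such genes. Of 100 simulated lists with no shift, 3 lay outside the central 95%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. Control spots and probes with no gene symbol were left out of the comparisons.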

Results

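Gene expression was measured in MIA PaCa-2 cells, an established human pancreatic cancer line, grown either as a flat monolayer or as spheroids, which are compact clusters of cells grown in 3 dimensions. A whole-genome oligonucleotide array with 1 colour (Cy3) was used for each of 3 groups: monolayer cells harvested at 100% confluency, spheroids collected on day 6 and spheroids collected on day 13. Each group had 1 array, so no difference has a replicate check, no test between groups was possible and no p-value is given. Error is therefore given only as the spread within an array and between probes of a gene. Of the probes, 69.3% were well above background on the monolayer array, 64.3% on the day 6 array and 67.7% on the day 13 array, and no spot was saturated. The 75th percentile over probes of the log2 signal, used for the scaling, was 10.17 for monolayer, 8.72 for spheroid day 6 and 8.60 for spheroid day 13, so by this measure the monolayer array was 2.73 times as bright as the day 6 array and 2.98 times as bright as the day 13 array. Genes dim on the spheroid arrays differed less than that before scaling: those at 32 to 64 signal units had an unscaled median log2 difference of -0.13 on day 6 and 0.00391 on day 13, and those at 512 to 1024 units of -1.45 and -1.60. Replicate spots of a probe within an array differed by a median SD of 0.05 to 0.06 log2 units where the log2 signal was above 8, and by 0.32 to 0.39 where it was below 5. The number of arrays limits the precision of every difference.

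**Figure D1:**
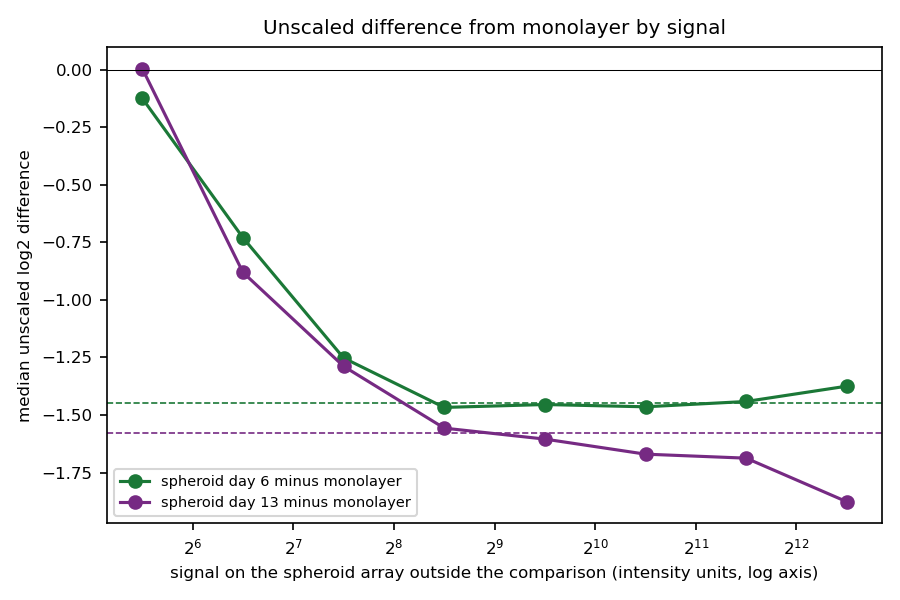
Median log2 difference from monolayer before scaling (vertical axis) against the signal on the spheroid array outside the comparison (horizontal axis, log scale), for spheroid day 6 and spheroid day 13, with the differences of the 75th percentiles as dashed lines. The dimmest genes shown lie at -0.13 and 0.00391, those at 64 to 128 units at -0.73 and -0.88, and the brightest, at 4096 to 8192 units, at -1.37 and -1.88, beside dashed lines at -1.45 and -1.58.

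The series asked which genes differ with the culture condition. In spheroids on day 6, genes of cell division were far below their monolayer level, and genes known to be induced by low oxygen were far above it. CCNB1, the cyclin that drives entry into mitosis, was 53.5-fold lower (log2 difference -5.74, with its other probe at -2.95), and CDC45, part of the helicase that opens replicating DNA, was 37.7-fold lower (-5.24). CA9, a carbonic anhydrase induced by hypoxia, was 65.0-fold higher (6.02), and NDRG1, another hypoxia-induced gene, had a difference of 5.50. The highest differences on day 6 included TREM1, a receptor of myeloid cells, at 272-fold (8.09, with its other probe at 6.22), OLAH, a thioesterase of fatty acid synthesis, at 178-fold (7.48) and LCN1, tear lipocalin, at 145-fold (7.17).

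Further genes among the highest on day 6 were HCAR3, a hydroxycarboxylic acid receptor (7.14), MARCO, a scavenger receptor (6.76), CEMIP, a hyaluronan-binding protein (6.44, with its other probe at 2.20), PAEP, which encodes glycodelin (6.41), SHC2, a signalling adaptor (6.24), AREG, a ligand of the EGF receptor (6.16), and ACKR3, an atypical receptor for the chemokine CXCL12 (5.79). HCAR3 is nearly identical to HCAR2, so its value is uncertain. MMP1, an interstitial collagenase, CXCR4, the other receptor for CXCL12, and IL13RA2, a decoy receptor for interleukin 13, were not well above background in monolayer and were at least 812-fold, 380-fold and 111-fold higher in spheroids.

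Every one of the 29 measured members of the mitosis list was at least 2-fold lower on day 6, with a median of -4.17 against 0.19 for random lists matched on mean signal, below all 10000 of them, and 3 of the values were lower bounds. BUB1, a spindle checkpoint kinase, was not well above background on day 6 and at least 73.9-fold lower. BUB1B was at -5.05, the spindle-associated HMMR at -4.86, CDC20, an activator of the anaphase-promoting complex, at -4.77, BIRC5 (survivin) at -4.69 and DLGAP5 at -4.64. In the DNA replication list 28 of 30 members were lower and 2 were within 2-fold, and the median of -2.79 was also below all 10000 random lists. GINS2 was at least 56.7-fold lower, and RRM2, a subunit of ribonucleotide reductase, was at -4.36. Outside these lists, the exonuclease EXO1 (-5.19), the mitotic kinase PBK (-5.13), KIF14 (-4.84), SPC25 (-4.83) and the recombination gene RAD54L (-4.64) were among the 12 lowest differences, and FAM83D was at least 52.7-fold lower. Cyclin-dependent kinase inhibitors and quiescence genes were higher in 7 of 11 members and lower in 1, with CDKN1C at 4.97, BTG1 at 3.78 and CDKN1A (p21) at 2.28. Their median of 1.16 exceeded 9977 of the 10000 random lists.

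Hypoxia response genes were higher in 32 of 33 measured members and lower in 0, with a median of 2.58 against -0.06 for matched random lists, above all 10000. PFKFB4, a regulator of glycolysis, was at 4.65 and ANKRD37 at 4.61. Of the 16 glycolysis genes 5 were higher, among them ENO2 (4.55), HK2 (3.56) and PGK1 (1.64), and PFKM was lower (-1.77). The glycolysis median of 0.66 exceeded 9882 random lists. Genes of oxidative phosphorylation and the citric acid cycle were lower in 23 of 33 members and higher in 0, with FH at -2.75, ATP5F1B at -2.36 and CYC1 at -2.12. Ribosome biogenesis and MYC target genes were lower in 17 of 20 members, with BOP1 at -2.55, NOP16 at -2.52 and NOP56 at -2.02. Both medians, -1.33 and -1.57, were below all 10000 random lists. Cytosolic ribosomal proteins stayed within 2-fold in 29 of 30 cases (median 0.16, below 0 under 4 alternatives), and the exception, RPL13 (1.04), had probes of opposite sign.

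Stress and signalling lists differed in direction. Endoplasmic reticulum chaperones were higher in 12 of 20 members (median 1.26), with DNAJB9 at 3.65 and HSPA5 (BiP) at 2.33, and p53 targets in 12 of 18 (1.32), with SULF2 at 4.83 and GDF15 at 2.71. Lysosome and autophagy genes were higher in 12 of 21 and lower in 2 (1.22), with TFEB, a transcription factor for lysosomal genes, at 3.07 by its brightest probe and 0.03 by the other. These 3 medians were above all 10000 random lists. The amino acid starvation response was higher in 12 of 23 members (median 2.14-fold), with DDIT3 (CHOP) at 3.73 and ATF3 at 3.15 (1.40 to 3.41 over its 4 probes), and immediate early genes in 10 of 19, with 1 lower (1.07), with EGR2 at 4.54 and JUN at 3.45. TGF-beta targets were higher in 8 of 14 and lower in 1 (1.66), led by INHBA, the activin A subunit, at 5.47, while CCN2 was at -4.34. Metallothioneins, which bind zinc and are hard to tell apart by probe, were higher in 9 of 10 (1.74). Each of the last 4 medians exceeded 9999 random lists. In the list called glucose-sensing thioredoxin-interacting proteins (TXNIP, ARRDC3, ARRDC4, MLX, MLXIP and MLXIPL), 4 of 6 genes were higher (1.53, above 9990 random lists). TXNIP was at 4.84 and ARRDC4 at 3.34. Not all members of this list are thioredoxin-interacting proteins. Inflammatory cytokines and NF-kB targets were higher in 10 of 23 and lower in 2 (0.66, above 9903 random lists), with PTGS2 (COX-2) at 3.81 and IL1B at 3.25, and IL11 at least 31.7-fold higher.

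Heat shock genes were lower in 12 of 16 members and higher in 1 (median -1.37, below all 10000 random lists), with HSPH1 at -2.08 and HSP90AA1 at -1.88, while CRYAB was at 1.75. Cholesterol synthesis genes were lower in 11 of 24 and higher in 2 (-0.82, above 10 random lists), with ACAT2 at -2.67. NRF2 and oxidative stress genes were lower in 8 of 20 and higher in 2 (-0.63, above 151 random lists), with NQO1 at -1.65. The list of drug transporters and gemcitabine metabolism had 7 of 16 members lower and 1 higher (-0.57, above 137 random lists), RRM1 being at -3.01 and CDA, cytidine deaminase, at 2.92. Its lowest members, RRM2 and RRM1, also belong to the DNA replication list, so its rank is not separate from the cell division result. Fatty acid synthesis (6 of 13 lower, median -0.70), YAP and TEAD targets (7 of 16 lower and 2 higher, -0.54), stem cell associated genes (4 of 16 lower and 3 higher, -0.18), interferon response (6 of 24 lower and 5 higher, 0.09) and reference genes (2 of 15 lower and 3 higher, -0.27) had medians within the central 95% of random lists. CCN1, a YAP target, was at -3.53.

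Epithelial genes (5 of 16 higher and 1 lower, median 0.40), mesenchymal genes (7 of 17 higher and 1 lower, 0.63), extracellular matrix (11 of 25 higher and 1 lower, 0.54), integrins and focal adhesion (5 of 19 higher and 1 lower, 0.18) and the BCL2 family and apoptosis list (9 of 21 higher and 3 lower, 0.53) were also within that range on day 6. DSP, a desmosome protein, was at 2.48, fibronectin FN1 at 2.25, and the collagens COL6A2 and COL5A1 at 3.46 and 3.26. ITGB3, an integrin subunit, was at least 53.9-fold higher. Neuroendocrine genes were higher in 5 of 10 members and lower in 1 (median 1.20, above 9882 random lists), with SCG5 at least 50.7-fold higher. Markers of fibroblasts, endothelium and blood cells, included as a check for other cell types, were higher in 9 of 10 measured members, with a median of 1.55 against 0.63 for random lists of equally dim genes, above 9834 of them. DCN was at least 5.35-fold higher and CD3E at 1.94. Pancreatic lineage genes were higher in 7 of 10 (median 1.23), within the central 95% of random lists. The neuroendocrine and drug transporter lists each stayed outside the central 95% under 7 of 12 alternatives for the values and the other cell type list under 8 of 11, and the glycolysis and inflammatory lists came inside it with no matching on signal. Of the lists within that range on day 6, extracellular matrix (inside under 8 of 12 alternatives for the values), mesenchymal (11 of 12) and pancreatic lineage (9 of 11) otherwise ranked above it, YAP and TEAD targets (8 of 12) below it, and fatty acid synthesis below it with no matching. The medians of the epithelial, extracellular matrix, integrin and BCL2 family lists were below 0 with each array's median as the reference, at -0.22, -0.08, -0.43 and -0.08, and the epithelial median also in the upper 50% of genes by signal (-0.51). The interferon response median was below 0 under 6 alternatives, and that of the stem cell associated genes was 0.33 with no filter and no floor.

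On day 6, 3788 of 15215 measured genes were at least 2-fold higher and 2252 at least 2-fold lower than in monolayer, so 62.7% of the differing genes were higher, and the median of all genes was 0.12. This split depended on the scaling and the filter. The share higher was 30.9% with each array's median as the reference, 47.9% with quantile normalization, 45.8% with cyclic loess and 46.7% with normexp background and quantile normalization, against 77.1% with no filter and no floor, and the median of all genes moved to -0.35 with each array's median. List medians are therefore ranked among random lists of equal signal.

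**Figure D2:**
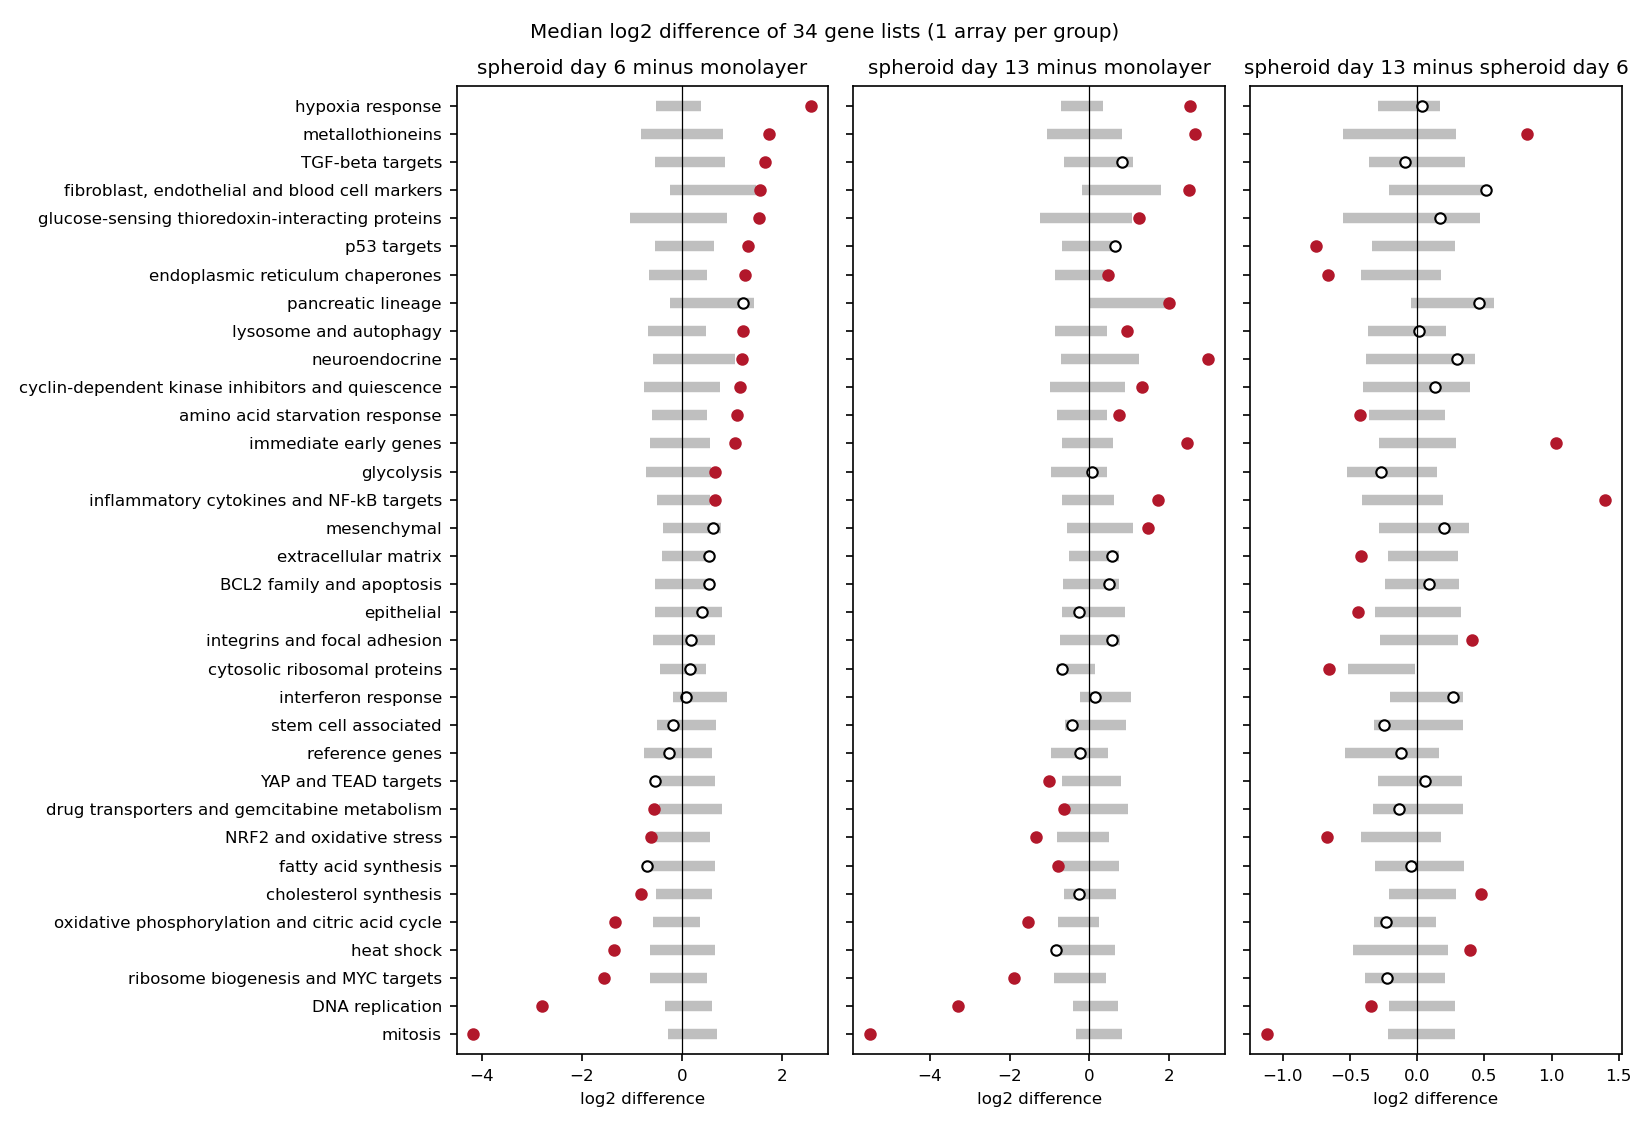
Median log2 difference (horizontal axes, on different scales) of the measured members of 34 gene lists (vertical axis) for the 3 pairs of arrays; grey bars span the central 95% of 10000 random lists matched on mean signal, and filled points lie outside them. The mitosis list is lowest in both comparisons with monolayer, at -4.17 and -5.49, and the hypoxia response list lies at 2.58 and 2.52.

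In spheroids on day 13, cell division genes were again far below monolayer and hypoxia genes above it, and genes of matrix proteases and a cytokine were among the highest. The collagenase MMP1, the stromelysin MMP10 and IL24, a cytokine of the interleukin 10 family, were not well above background in monolayer and at least 11375-fold, 3266-fold and 3844-fold higher on day 13. HCAR3 was 894-fold higher (9.80), TREM1 344-fold (8.42), AMPD3, an AMP deaminase, 272-fold (8.09) and SPINK1, a trypsin inhibitor, 150-fold (7.23). BIRC5 was 231-fold lower (-7.85), CENPM, a centromere protein, 183-fold (-7.51, with its other probe at -4.92) and AKR1B10, an aldo-keto reductase that reduces retinaldehyde, 147-fold (-7.20).

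Other genes among the 12 highest on day 13 were OLAH (7.82), the antisense transcript ZMIZ1-AS1 (7.56), MARCO (7.38), AREG (7.38), ACKR3 (7.33), EGR2 (7.19) and MEI1 (7.17). The lowest were joined by CDC45 (-7.35), the spindle protein ASPM (-7.26, other probe -5.00), thymidine kinase TK1 (-7.14), EXO1 (-6.92), HMMR (-6.80), CCNB1 (-6.67, other probe -3.09), HOPX (-6.59, with its other probe at -0.06) and TROAP (-6.51, other probe -2.67). AKR1B15 (-6.53) is nearly identical to AKR1B10, so the pair cannot be counted as separate. PCLAF, HJURP and CCNB2, all genes of dividing cells, were not well above background on day 13 and at least 525-fold, 295-fold and 293-fold lower.

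All 29 measured mitosis genes and 28 of 30 DNA replication genes were lower on day 13, with medians of -5.49 and -3.30, both below all 10000 random lists, and 13 of the mitosis values were lower bounds. Hypoxia response genes were higher in 31 of 33 (median 2.52, above all 10000 random lists), with NDRG1 at 5.85, ADM at 5.25 and HILPDA, a lipid droplet protein, at 4.66. Oxidative phosphorylation and citric acid cycle genes were lower in 28 of 33 (-1.55) and ribosome biogenesis and MYC targets in 17 of 20 (-1.90), both below all 10000 random lists. NRF2 and oxidative stress genes were lower in 13 of 20 and higher in 2 (-1.33, above 3 random lists), with NQO1 at -4.04 and TKT, a pentose phosphate enzyme, at -3.45. YAP and TEAD targets were lower in 8 of 16 and higher in 2, with a median above 48 random lists, with CCN2 at -4.33 and MYOF at -3.91, while F3, tissue factor, was at 3.66.

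Inflammatory cytokines and NF-kB targets were higher in 14 of 23 members and lower in 1 on day 13 (median 1.73), immediate early genes higher in 16 of 20 and lower in 2 (2.44) and metallothioneins in 9 of 10 (2.65), each above all 10000 random lists. CSF2 (GM-CSF) was at least 95.8-fold higher, PTGS2 was at 6.12, IL1B at 5.33, BIRC3 at 4.68, FOS at 4.61 and EGR1 at 4.28. Neuroendocrine genes were higher in 6 of 10 and lower in 1 (2.98, above all 10000 random lists), with SYP, synaptophysin, at 5.32 and SCG5 at least 1331-fold higher. Mesenchymal genes were higher in 9 of 17 and lower in 1 (1.46, above 9969 random lists), with ITGA5 at 3.99 and SNAI2 at 3.87, but TGFBI at -4.85. Markers of fibroblasts, endothelium and blood cells were higher in 9 of 11 and lower in 1 (median 5.65-fold higher, above 9998 random lists of equally dim genes), with CSF1R 15.7-fold higher (3.98) and DCN at least 129-fold higher, its other probe giving 2.30. Endoplasmic reticulum chaperones were higher in 8 of 20 and lower in 2 (0.47 against -0.27, above 9831 random lists), a sign that turned to -0.27 with each array's median as the reference. Among stem cell associated genes 6 of 16 were lower and 4 higher (-0.45, within the range of random lists), but the median ranked below that range under 6 of 12 alternatives and was 0.53 in the upper 50% of genes by signal, an alternative added after the data were seen. ALDH1A1 was at -6.36 and SOX2 at -3.42, while CXCR4 was at least 930-fold higher. Lysosome and autophagy genes (10 of 21 higher and 2 lower, 0.94, above 9998 random lists), cyclin-dependent kinase inhibitors (7 of 11 higher and 2 lower, 1.31, above 9981) and the amino acid starvation response (11 of 23 higher and 4 lower, 0.75, above 9972) were high against random lists, as were the glucose-sensing proteins (3 of 6 higher, 1.26, above 9884) and pancreatic lineage genes (11 of 14 higher, with a median above 9788). Drug transporters (7 of 16 lower and 1 higher, -0.63, above 219) and fatty acid synthesis (6 of 14 lower and 2 higher, -0.79, above 248) were low, but with normexp background the drug transporter median turned to 0.0462. The lowest members of the drug transporter list were again RRM2 and RRM1, which the DNA replication list also holds. Of the day 13 lists outside the central 95%, fatty acid synthesis stayed outside under only 3 of 12 alternatives for the values and pancreatic lineage under 3 of 11, drug transporters under 7 of 12, chaperones and mesenchymal genes under 8 of 12 each and amino acid starvation under 11 of 12. Further lists came inside it with no matching on signal, namely cyclin-dependent kinase inhibitors, lysosome and autophagy genes and the glucose-sensing proteins. Some lists outside the central 95% on day 6 were inside it on day 13. They included glycolysis (5 of 16 higher and 2 lower, median 0.07) and p53 targets (7 of 18 higher and 2 lower, 0.64). Others were TGF-beta targets (7 of 15 higher and 5 lower, 0.83) and cholesterol synthesis (9 of 24 lower and 2 higher, -0.26). Heat shock genes (7 of 16 lower and 1 higher, -0.84, above 270 random lists) lay just inside it.

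In all, 5035 of 15799 measured genes were at least 2-fold higher and 2813 lower on day 13 than in monolayer, 64.2% of the differing genes being higher, with a median of all genes of 0.24. The share higher was 35.3% with each array's median (median of all genes -0.38), 49.5% with quantile normalization, 47.1% with cyclic loess, 46.4% with normexp background and quantile normalization and 74.6% with no filter and no floor.

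Between the spheroid times, the cytokine gene IL24 was 78.6-fold higher on day 13 (6.30), IL1RN, the interleukin 1 receptor antagonist, 56.8-fold (5.83, with its other probe at 0.78), MMP10 42.7-fold (5.42), the alarmin IL33 33.4-fold (5.06) and MMP3 20.4-fold (4.35). CTSZ, the lysosomal protease cathepsin Z, was 153-fold lower on day 13 than on day 6 (-7.26), SEMA3D, a secreted guidance factor, 56.5-fold (-5.82), FGG, the fibrinogen gamma chain, 46.1-fold (-5.53) and TGFBI, a matrix protein, 44.6-fold (-5.48). OLFML2A was at -6.77, but its other probe had the opposite sign.

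RCSD1 (5.27), PNLIPRP3 (4.78), SCG5 (4.71), the proteoglycan DCN (4.59, other probe 0.52) and MROH9 (4.53) were also among the highest, as were FRG2C (5.33) and FRG2 (5.29), copies of a repeated gene that probes cannot separate. The chemokine CCL3 and IL36G, an interleukin 1 family cytokine, were not well above background on day 6 and at least 51.4-fold and 18.1-fold higher on day 13. Among the lowest were AKR1B10 (-5.22), SLF1 (-4.84), ALDH1A1 (-4.62), the neuropeptide NTS (-4.62), LCN1 (-4.56) and BDNF (-4.48). PDK4, a kinase that holds back pyruvate oxidation, ESM1 and ST8SIA4 were not well above background on day 13 and at least 40.8-fold, 25.1-fold and 21.7-fold lower.

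Inflammatory cytokines and NF-kB targets were higher on day 13 than on day 6 in 12 of 21 members and lower in 1 (median 1.40), and immediate early genes in 11 of 20 (1.04). Metallothioneins had 1 of 10 members past 2-fold (0.81). All 3 medians were above all 10000 random lists. Cholesterol synthesis genes were higher in 5 of 24 (0.47, above 9999 random lists), with INSIG1, a sterol-responsive regulator, at 3.74 and LSS at 1.45. Mitosis genes were lower in 17 of 26 (-1.12, below all 10000 random lists) and DNA replication genes lower in 8 of 26 and higher in 1 (-0.35, above 30), and with normexp background the medians were -0.12 for mitosis and -0.12 for DNA replication, both inside the central 95%. p53 targets were lower in 7 of 18 (-0.75, above 1 random list), with BAX at -2.92 (other probe -0.78) and GDF15 at -2.04, and NRF2 and oxidative stress genes in 7 of 20 (-0.67, above 4). Endoplasmic reticulum chaperones (5 of 20 lower, -0.67, above 10), epithelial genes (6 of 16 lower, -0.44, above 46) and extracellular matrix (6 of 24 lower and 3 higher, -0.42, above 5) were also low against random lists. Cytosolic ribosomal proteins were within 2-fold in 28 of 30 members (-0.66 against -0.27, above 10), and the amino acid starvation response was lower in 6 of 23 and higher in 1 (-0.43, above 80). The extracellular matrix list came inside the central 95% with normexp background and the amino acid starvation response with cyclic loess. Heat shock genes (2 of 15 higher, 0.39, above 9978) and integrins and focal adhesion (5 of 19 higher and 4 lower, 0.41, above 9963) were high, the former within the central 95% with no matching on signal. FN1 was 8.02-fold lower, COL5A2 at -2.03 and CLDN3 at -1.69. Hypoxia response genes had 28 of 33 members within 2-fold and a median of 0.03, which was -0.15 with normexp background.

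Over all genes, 817 of 15120 were at least 2-fold higher and 1089 lower on day 13 than on day 6 (42.9% of the differing genes higher), and the median of all genes was 0.09. With each array's median as the reference, 29.9% were higher, and with no filter and no floor 53.2%, so that higher genes outnumbered lower ones.

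Against monolayer, 3110 genes were at least 2-fold higher and 1881 at least 2-fold lower at both spheroid times, 4991 in all among 15138 genes measured in both comparisons, and 33 genes differed in opposite directions. Independent lists of the same sizes would share 1072 higher and 418 lower genes. The differences at the 2 times correlated across genes, which are not independent replicates, with r = 0.87 and a covariance of 1.82. Unchanged arrays simulated with spot noise against the same monolayer array gave r = 0.50, a covariance of 0.01, and on average 1.70 genes higher and 1.76 lower at both times. These simulated arrays held no variation between cultures and no difference in brightness, so they show only what spot noise would give. The monolayer array cannot be split, so part of the excess may come from the shared control. The scaling is shared too, adding 1.45 log2 units to the day 6 differences from monolayer and 1.58 to those on day 13. Genes dim on the spheroid arrays differed little before scaling, so this shift alone can carry them past 2-fold higher at both times. Among the upper 50% by signal (7569 genes, chosen after seeing the data), 893 were higher at both times, against 207 for independent lists. Lower at both were 1232, against 362.

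**Figure D3:**
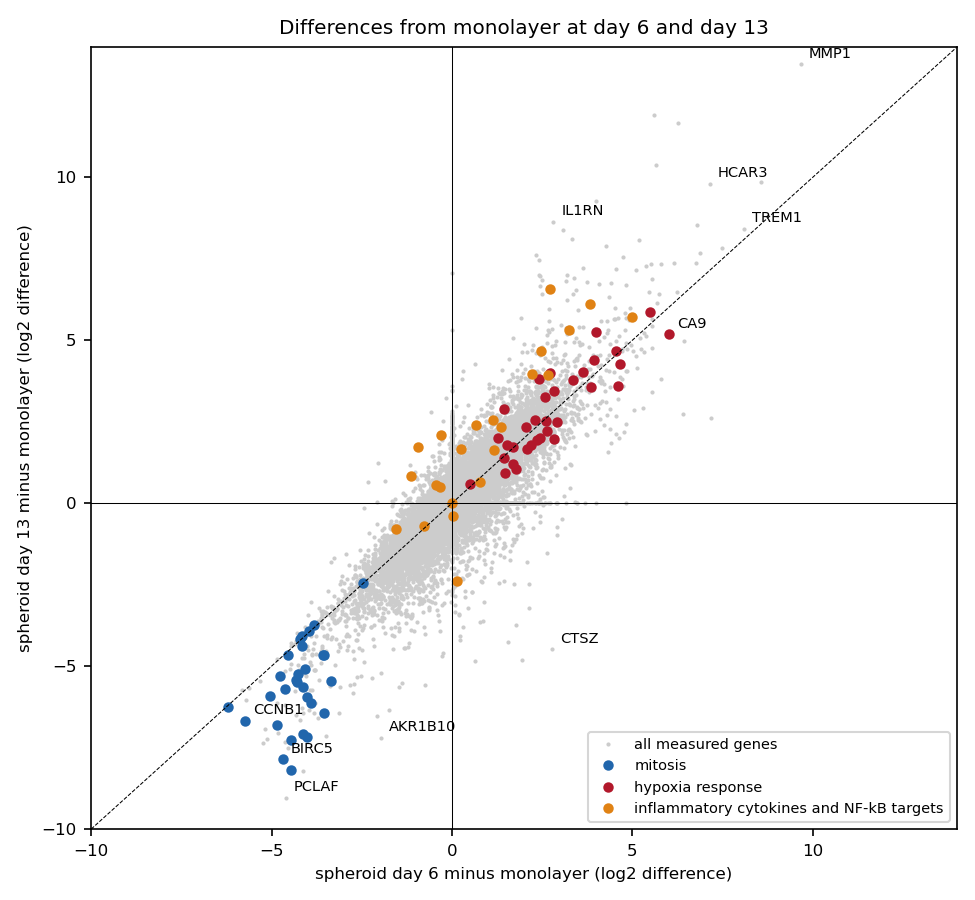
Log2 difference from monolayer on day 13 (vertical axis) against day 6 (horizontal axis) for each measured gene, with the mitosis, hypoxia response and inflammatory lists in colour and equality as a dashed line. Mitosis genes lie at the lower left, hypoxia genes near the line at the upper right, and CTSZ lies at 2.78 on day 6 and -4.48 on day 13.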

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

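The tests on the additive signal, on the scaling of the cell division lists and on the split of leukocyte genes by monolayer signal were chosen only after the results were seen.

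Genes at least 2-fold higher than monolayer at one spheroid time and at least 2-fold lower at the other were singled out, and the difference between the times was not tested, as each had 1 array. Of 33 such genes, 31 were higher on day 6 and lower on day 13 than monolayer. Log2 differences on day 6 and day 13 were 2.78 and -4.48 for CTSZ, 2.14 and -2.47 for NTS, 2.14 and -3.21 for PDK4 (a bound on day 13), 1.95 and -4.82 for OLFML2A (whose other probe had the opposite sign on day 13), 1.78 and -3.74 for FGG, and 1.56 and -4.26 for SEMA3D. CD14, a monocyte marker, was at 1.44 and -1.64, the growth arrest gene GAS1 at 1.16 and -1.51, and IFITM1, an interferon-induced gene, at 1.12 and -1.81.

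Probes with no gene symbol, which no comparison used, also held large differences. At least 8-fold higher were 76 of them on day 6 and 127 on day 13 against monolayer, and 11 and 40 were at least 8-fold lower. On day 13 against day 6, 3 were higher and 18 lower by that size.

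More genes were higher than lower in each spheroid array against monolayer. A candidate explanation is an additive signal of similar size on every array, which the scaling of the dimmer arrays enlarges, and in the upper 50% of genes by signal 44.1% and 42.2% of the differing genes were higher. Genes at 32 to 64 units on the spheroid array outside the comparison, taken with no filter, had an unscaled median log2 difference of -0.13 on day 6 and 0.00391 on day 13, while genes at 512 to 1024 units were at -1.45 and -1.60, close to the -1.45 and -1.58 between the 75th percentiles. This way of sorting was settled on after others had been tried, among them one whose filter fixed its own outcome. With normexp background 65.5% on day 6 and 68.9% on day 13 were higher, and with 30 units subtracted from every probe 57.2% and 59.7%. Neither run can decide the question. The normexp offset of 50 is itself a signal added to every array. With the 30 units subtracted, values below 10 were set to 10, and a gene measured at 10 on both arrays is called higher by the scaling alone. Negative control spots had a median processed signal of 5.54 units on the monolayer array, 6.91 on day 6 and 6.61 on day 13. These lie below the 32 to 64 units of the dim genes. Whether gene probes carry a larger added signal than these control spots was not tested. An additive signal and the culture condition, which was not tested, both stay open.

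The mitosis and DNA replication lists were lower in both spheroid arrays. A trend with signal intensity, or the choice of scaling and background, is argued against by every alternative run: the list median minus that of matched random lists came no nearer to 0 than -3.46 and -3.84 for mitosis, and -2.33 and -2.82 for DNA replication, on day 6 and day 13, below the central 95% of random lists throughout. The culture condition stays open, as does any peculiarity of the single monolayer array. Neither was tested.

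The myeloid genes TREM1 and MARCO were higher in both spheroid arrays, and RNA from blood leukocytes was weighed as the source. Of 14 abundant leukocyte genes (13 on the array), 8 were well above background on the day 6 array and 8 on day 13, which met the bound of at least 50% set before this count was seen, so the planned test came out in favour of leukocyte RNA. A split added after that result weakens it: 5 of the genes were also well above background in monolayer. Among them was PTPRC, which the marker list of other cell types holds too, at 1.41 and 1.83 over monolayer by the brightest of its 4 probes. Before scaling, the PTPRC signal was 93.1 units in monolayer, 90.9 on day 6 and 111 on day 13. Its differences thus came mostly from the 1.45 and 1.58 log2 units that the scaling added. Of the 8 genes not well above background in monolayer, 3 appeared on each spheroid array. CD48, CD52, CYBB and LAPTM5 were well above background on no array. Genes this near background cannot exclude a small share of leukocyte RNA. Unscaled signals in monolayer, on day 6 and on day 13 were 6.65, 26.0 and 34.9 units for LAPTM5 and 16.3, 21.6 and 28.6 for CD52. For CD48 they were 5.38, 6.68 and 6.57, and for CYBB 5.59, 7.02 and 6.81. The cultures described above were of an established cancer line, with no blood cells named, so the design gives no source for leukocytes. The count itself cannot separate leukocyte RNA from expression by the cancer cells. Of its 8 genes, 5 were also well above background in monolayer, many of the genes lie near background, and levels of different probes cannot be set against each other.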

How the results depend on the processing

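The upper 50% of genes by signal and the subtraction of 30 units were chosen after seeing the data. Of the named genes at least 2-fold different, none turned its direction under any alternative run except RPL13 on day 6, which was at -0.14 with normexp background and quantile normalization. In all, 4570 of 4572 values of 421 gene differences kept their sign, and 4434 stayed at least 2-fold. Of the 421, 71 fell under 2-fold in at least 1 alternative. These genes were named by the size of their difference, so their stability says little about other genes past 2-fold. With cyclic loess, 2269 of the 3788 higher and 2064 of the 2252 lower genes on day 6 remained, and no gene turned from higher to lower there. With the mean over all probes of a gene, 1 gene on day 6, 4 on day 13 and 1 between spheroid times turned. Of 22 gene lists outside the central 95% of random lists on day 6 (8 low and 14 high), 7 and 12 stayed outside under every alternative for the values, on day 13 6 of 8 and 9 of 13, and between spheroid times 5 of 9 and 6 of 6. With 10 bins and no matching counted too, 7 and 10, 6 and 6, and 5 and 5 stayed. None crossed to the opposite side. Of the lists inside the central 95%, 8 of 12 on day 6, 5 of 13 on day 13 and 13 of 19 between spheroid times stayed inside under every alternative for the values, and 7, 5 and 11 with the rank alternatives too. The sign of the median turned under at least 1 alternative in 7, 7 and 8 of these. Counts moved more. With each array's median, 1999 genes were higher and 4477 lower on day 6, and 2918 and 5360 on day 13, because the reference moved. Quantile normalization gave 2223 higher on day 6 and 3105 on day 13, and cyclic loess 2405 and 3103. Normexp background gave 542 higher and 671 lower between the spheroid times. Together with quantile normalization it gave 1407 higher on day 6, 1878 on day 13, 503 higher and 713 lower between spheroid times, and 2342 genes at least 2-fold different from monolayer in the same direction at both spheroid times. No filter and no floor, which adds dim genes, gave 8049 higher on day 6, 8786 on day 13, 1545 higher and 1358 lower between spheroid times (the excess thus turning to higher genes) and 9360 at both times. In the upper 50% of genes by signal, 1167 were higher and 1478 lower on day 6, and 1415 higher on day 13. There 294 were higher and 600 lower between spheroid times, and 2132 the same at both. Fewer genes were counted, but the lower 50% also held more of the higher genes, with 2621 higher and 774 lower on day 6. With 30 units subtracted, 1500 were higher and 1516 lower between spheroid times. Of the lists outside the central 95%, 2 medians turned, both on day 13, that of the endoplasmic reticulum chaperones to -0.27 with each array's median and that of the drug transporter list to 0.0462 with normexp background. For quantile normalization, cyclic loess, normexp background, the 30 units and the values that turned, the cause was not tested. A block for slide or scan was not run, as all arrays share both and no residual degrees of freedom remain. No paired analysis was possible because each group has 1 array. Signal over background limits dim genes most: on the dimmer spheroid arrays a low value is more often only a bound.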

Other observations

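The gene families here, their members and the ranks were chosen after the named genes were seen, so they are not independent evidence. Interleukin 1 family cytokines were higher in 10 of 11 measured members on day 13 and lower in 1 (median 4.39 against 0.73 for matched random lists, above all 10000). IL36B was at least 237-fold and IL33 at least 176-fold higher, while IL18 was the member that was lower. Their median lay between 2.54 and 5.33 over the alternatives. Matrix metalloproteinases were higher in 5 of 14 members on day 13 against day 6 (median 0.74, above 9998 random lists, and 0.39 to 1.47 over the alternatives, with a rank inside the central 95% under at least 1), with MMP9 at 1.58. Of 7 ligands of the EGF receptor, 4 were higher and 1 lower on day 13 against monolayer, with EREG at least 23.5-fold higher beside AREG at 7.38, and their median of 1.49 was within the central 95% of random lists but above it under at least 1 alternative.

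Aldo-keto reductases, which reduce aldehydes and ketones, were lower in 8 of 9 measured members on day 6 (median -1.61) and in 9 of 11 on day 13, with 2 higher (-2.14), both below all 10000 random lists. The medians stayed at or below -1.51 and -1.76 under every alternative run. AKR1C3 was at -1.55 and -2.97, and as members of this family are similar in sequence, probes do not surely separate them. S100 genes were higher in 8 of 14 and lower in 1 on day 6 (1.34, above 9999 random lists, and 0.73 to 1.47 over the alternatives), with S100A7 at 4.82 and S100A9 at 4.72, while S100P was at 1.81 on day 6 and -0.99 on day 13. Serpins of clade B (2 of 6 higher and 2 lower) and the solute carrier 7 family (5 of 5 within 2-fold) were within the range of random lists on day 6, with medians whose sign turned under some alternatives. HCAR2, nearly identical to HCAR3, was at 3.74 on day 6 and 6.80 on day 13.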
